A study of Mus musculus with 30 samples.

How the data were processed

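Liver RNA of 30 mice was measured on 1-colour oligonucleotide arrays (the 4x44K whole mouse genome design of Agilent), with 1 mouse per array. The labels name 2 inbred strains, C57BL/6 (B6) and DBA/2 (D2), and 3 diets that differed in iron. The balanced diet held 200 mg of iron per kg, the enriched diet 8.3 g per kg and the deficient diet less than 3 mg per kg. Each of the 6 groups held 5 mice, and the labels give every mouse its own animal code, so the replicates were separate animals. The numbers 1 to 5 within a group follow accession order, only name a mouse and pair no samples. The sex, the age, the length of feeding and the hour of sampling are not given in the sources used here.

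The deposited files are the scanner software's output for each array, and their values are fluorescence intensity on a linear scale. Per the file headers, the spots were read with Agilent Feature Extraction 9.1.3.1, while the labels name version 9.5.1. Per the file headers, the processed signal is a background-subtracted intensity, and no normalization between arrays had been applied to it. The value table deposited with the series holds the same processed signal intensity on a linear scale, neither centred nor scaled between arrays, with a largest difference of 0 from the array files. Its column medians ran from 58.9 to 117. Per the series' design text, the authors normalized between arrays by the quantile method, excluded genes that were dim in too many mice of either strain, and fitted strain, diet and their interaction by a moderated analysis of variance with permutation p-values. That package (R/maanova) was not run here, and limma's moderated tests took its place.

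Each array file held 43379 spots of genes and 1639 control spots. Control spots and spots with a population or uniformity outlier mark were left out, spots of 1 probe were averaged, and 41174 probes were left. The processed signals were normalized by the quantile method, raised to a floor of 13.9 (the median over arrays of the lowest signal marked well above background) and log2 transformed. A probe was kept when the software marked it well above background on at least 3 B6 arrays and at least 3 D2 arrays and every group had at least 3 values, which left 29991 probes. The mark holds where the background-subtracted signal exceeds 5 times the additive error, a different rule from the 2.6 standard deviations of the series' text, which was tried as an alternative. For a gene with more than 1 kept probe (6381 genes) the probe with the highest mean signal stood for it, and 21075 genes were tested.

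Gene names came from a table of RefSeq genes of assembly GRCm38.p6, used for names only: 22951 probes matched by accession, 6659 by a current symbol, and 11564 kept the name in the array file. The files name no genome build, so no coordinates are given. Hamp and Hamp2 are near-identical in sequence, and cross-hybridisation between their probes was not measured, so their separate levels are uncertain.

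All 30 arrays entered one limma fit (limma 3.58.1 in R 4.3.3; tables were read with Python 3.11.15) of 6 group means, with moderated variances and Benjamini-Hochberg adjustment over the 21075 genes at 0.05. The contrasts were enriched against balanced and deficient against balanced, each averaged over strains and within each strain, D2 against B6 averaged over diets, and the differences between strains of the enrichment and of the deficiency effect (D2 minus B6). F tests over the diet contrasts and over the interaction contrasts were added. Every adjusted p below comes from this limma fit unless another test is named. Averaged diet effects weigh both strains equally.

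In all, 36 gene lists with 575 genes, of which 546 were tested, were written down from general knowledge of liver, iron and their cell types. Each list was tested with limma's camera at its preset correlation of 0.01 against all other tested genes, adjusted over the 36 lists within a contrast. Alternatives were an estimated correlation within each list and limma's fry, which asks whether a list's genes move one way without comparing them with other genes. Of the 180 combinations of list and averaged comparison, camera passed 54, fry 54 and camera with an estimated correlation 8. The groups, contrasts, lists, rule for named genes and other settings were fixed before the data were examined. That rule named the 10 largest rises and 10 largest falls among genes that passed with the same sign in both strains (or all diets), the 5 smallest adjusted p of each interaction contrast, the genes of the series title and the hepcidin genes everywhere, and up to 4 members of each list described. Names that are only a clone or probe identifier were passed over. The title genes were chosen by the study on these samples, so their list is not independent evidence.

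The files record 10 slides and 3 scan days, with 5, 11 and 14 arrays on 3, 3 and 4 slides. Scan day was spread unevenly over the groups: day 1 held 1 B6 and 4 D2 arrays, and day 3 held 4 of 5 B6 enriched but 1 of 5 D2 balanced arrays. It is thus partly confounded with strain and diet but not fully, so slide and scan day were each added to the fit as blocks, and the contrasts were refitted within scan days 2 and 3. Scan day 1, with 5 arrays of 4 groups, was not fitted on its own. On scan day 2 the B6 balanced, B6 enriched and D2 enriched groups had 1 array each, and on scan day 3 the D2 balanced group had 1, so in the fits within a day these lone arrays are assumed to vary like the other groups. With the 6 groups in the model, 7021 of 21075 genes differed between scan day 3 and the other days.

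The other settings were 75th-percentile and cyclic loess normalization, normexp background correction, the deposited value table as it is, no dim-probe filter or a stricter one, every probe separately or a mean per gene, slide or scan day as a block, only the compared groups in the fit, an intensity trend with robust variances, array weights, a plain test without moderated variances (with and without adjustment), Storey's q, a minimum of 1.5-fold, and leaving out each mouse. The plain test is not the study's moderated permutation test. The looser filters, the fits within a scan day, the fit without the 3 balanced arrays least similar to their own group, and the list tests with blocks were added after the data were seen. Limma calls were also compared with up to 100 random regroupings of the mice per result.

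The fit was tested on simulated data: 200 of 21075 genes were changed by a known amount in 5 runs per size. For enriched against balanced 60.2%, 88.9% and 99.6% of genes changed by 0.5, 1 and 2 (log2) were recovered, for deficient against balanced 58.7%, 91.9% and 99.4%, and for D2 against B6 69.9%, 95.9% and 99.6%. For enrichment in B6 alone the shares were 35.3%, 77.1% and 97.5%, and for the difference of the enrichment effect between strains 15.1%, 59.5% and 90.3%. Between 4.44% and 7.13% of the calls were wrong. The simulated genes varied independently of each other, without slide or scan day effects, so these shares need not hold for the real calls. The number of arrays limits the precision. On each array between 63.1% and 78.8% of probes were marked well above background (median 70.3%), and at most 1 spot was saturated.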

Results

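Gene expression was measured in the livers of 30 mice on 30 single-colour arrays. The mice came from 2 inbred strains, B6 and D2, and were fed a balanced, an iron-enriched or an iron-deficient diet, with 5 mice in each of the 6 groups. On each array between 63.1% and 78.8% of probes stood well above background. The share was 70.4% ± 5.81 (SD, n = 5) in B6 balanced, 72.7% ± 3.74 in B6 enriched, 72.8% ± 3.66 in B6 deficient, 68.1% ± 1.47 in D2 balanced, 69.4% ± 3.24 in D2 enriched and 70.3% ± 4.45 in D2 deficient livers. The number of arrays limits the precision. The first principal component held 40.8% of the variance and parted the strains, and the next, with 14.6%, parted scan day 3 from the earlier scan days. Changes are given as log2 differences with limma's standard error (SE), and counts are of 21075 tested genes.

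**Figure D1:**
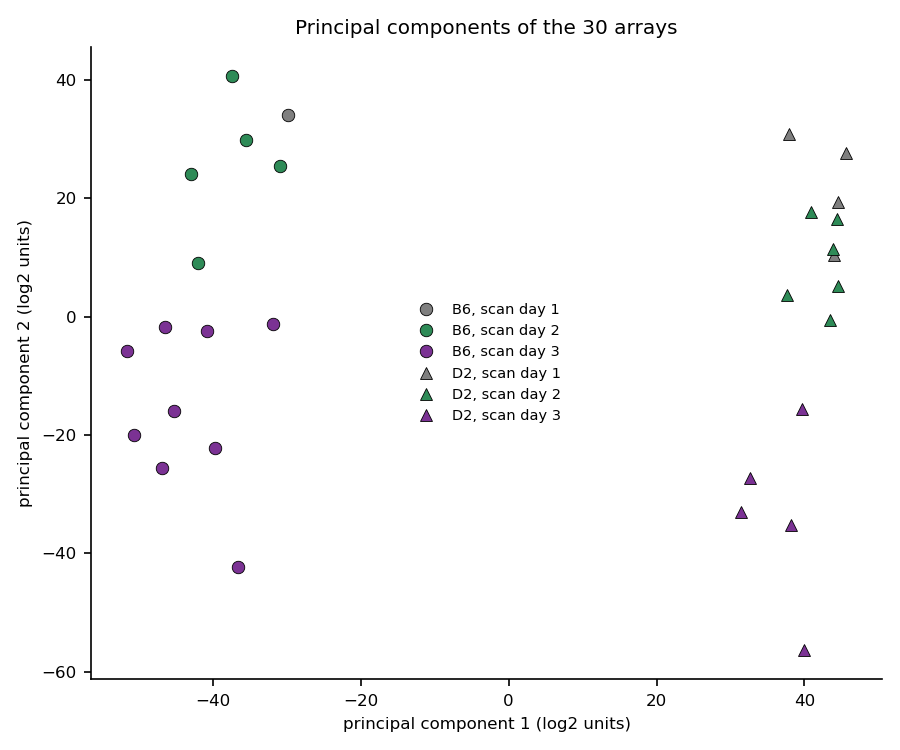
Scores of the 30 arrays on principal components 1 and 2 of the normalized log2 values (1 point per mouse; the symbol gives the strain, the colour the scan day). Component 1 (40.8% of the variance) parts the strains, and component 2 (14.6%) parts scan day 3 from days 1 and 2.

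The enriched against the balanced diet asked which liver genes respond to iron loading. Averaged over the strains, Bmp6, the secreted protein that drives hepcidin expression, was 2.30-fold higher on the enriched diet (log2 1.20, SE 0.059, adjusted p = 2.62e-13). Id1, Smad7 and Atoh8, known targets of BMP signalling, rose by 2.36 (SE 0.219, adjusted p = 1.43e-07), 1.72 (SE 0.153, adjusted p = 8.62e-08) and 1.53 (SE 0.142, adjusted p = 1.43e-07). All 4 were above the balanced mean of their strain in 10 of 10 enriched mice. In B6 livers the Bmp6 level went from 9.45 ± 0.08 (log2, SD, n = 5) to 11.06 ± 0.11, and in D2 livers from 8.99 ± 0.14 to 9.79 ± 0.16. Hepcidin, the hormone that blocks iron release into blood, is encoded by Hamp, and Hamp2 is its near-identical paralog. Hamp2 rose by 2.20 (SE 0.306, adjusted p = 8.64e-05). The change of Hamp was of similar size, 1.90 (SE 0.604), but missed the threshold (adjusted p = 0.102). Its SD was 1.39 in balanced D2 livers and 2.20 and 2.18 in the deficient B6 and D2 livers of the same fit. It passed with the compared groups alone (adjusted p = 0.0037) and without B6 deficient mouse 1 (adjusted p = 0.0319) or D2 deficient mouse 1 (adjusted p = 0.0396).

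The title genes, 4 of 4 of them higher (4 adjusted over the list alone), were chosen by the study on these samples, so this count is not independent evidence. Their median change was 1.62, and their list differed from all other genes (adjusted p = 2.86e-23, and adjusted p = 9.92e-06 with an estimated correlation). Of the hepcidin genes 1 of 2 rose (2 adjusted over the list alone; list adjusted p = 0.000154, and adjusted p = 0.0375 with an estimated correlation). Among the other components and targets of BMP signalling 7 of 29 rose, 1 fell and 21 did not pass (9 higher and 1 lower adjusted over the list alone). The inhibitors of differentiation Id3 (1.47), Id4 (1.34) and Id2 (0.91) and the inhibitory Smad6 (0.70) were among the rises. The list's median was 0.05 (adjusted p = 0.00127, but adjusted p = 0.223 with an estimated correlation). Sinusoidal endothelial markers, from the cells known as a main source of Bmp6, had a median change of 0.08 (adjusted p = 0.00285, but adjusted p = 0.223 with an estimated correlation). Of these 15 markers 1 rose, the scavenger receptor Stab1 (0.27), and 3 rose adjusted over the list alone.

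Genes of iron handling moved in both directions. Of 28 genes of iron transport and storage 4 rose, 2 fell and 22 did not pass (7 higher and 3 lower adjusted over the list alone; list adjusted p = 0.458, median 0.04). The ferritin light chain genes Ftl1 and Ftl2 each rose by 0.46, and Slc11a2, which carries ferrous iron into the cytosol, fell by 0.54 (adjusted p = 1.16e-05). Tfrc, the transferrin receptor whose transcript is known to be stabilised when iron is scarce, fell by 1.48 (SE 0.128, adjusted p = 5.94e-08), by 1.67 in B6 and 1.29 in D2. Of 8 heme synthesis genes 1 fell, the rate-limiting Alas1 (-0.69, adjusted p = 0.0425), while 1 rose and 4 fell adjusted over the list alone. The heme list's median was -0.11 (adjusted p = 0.0162, but adjusted p = 0.223 with an estimated correlation, and 0.0545 with scan day as a block).

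Of 23 targets of NRF2, the regulator of the oxidative stress response, 7 rose and 0 fell (11 and 0 adjusted over the list alone). Their median was 0.25 (adjusted p = 6.43e-11, and adjusted p = 0.0222 with an estimated correlation). The aldo-keto reductase Akr1b8 rose by 1.47 (SE 0.094, adjusted p = 9.65e-11), the glutathione transferase Gsta2 by 1.11, the exporter Abcc4 by 0.75, and Gclc, which starts glutathione synthesis, by 0.58. Of 7 genes of metal binding and zinc transport 1 rose, the metallothionein Mt1 (1.31, adjusted p = 0.00849; 3 adjusted over the list alone). That list's median was 0.32 (adjusted p = 0.0221, but adjusted p = 0.0836 with an estimated correlation, and 0.0657 with slide as a block). Of 24 cell cycle genes 2 rose, cyclin D1 (Ccnd1, 1.38) and the replication licensing factor Mcm2 (0.61), with 3 adjusted over the list alone. The cell cycle list's median was 0.21 (adjusted p = 3.02e-06, but adjusted p = 0.223 with an estimated correlation). By camera at its preset correlation, but not an estimated one, this list's enrichment effect was higher in D2 than in B6 livers. Its values are given under the other observations.

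Sex-biased, interferon response and unfolded protein response genes were tested as further lists. Of 16 male-biased liver genes 5 fell and 11 did not pass (9 lower adjusted over the list alone), with a median of -0.33 (adjusted p = 6.36e-11, and adjusted p = 0.0375 with an estimated correlation). Among them were the steroid-metabolising Hsd3b5 (-3.62, adjusted p = 0.000127, lower in 7 of 10 mice), the uptake transporter Slco1a1 (-1.84), the peroxisomal Nudt7 (-0.85) and the urinary protein gene Mup3 (-0.42, adjusted p = 0.000905). These averages came from B6 livers, with -7.09, -3.72, -1.58 and -0.78 there against -0.15, 0.04, -0.11 and -0.05 in D2 livers. Of 16 female-biased genes 1 rose, the sulfotransferase Sult3a1 (1.06, adjusted p = 0.0427, higher in 6 of 10 mice; 6 adjusted over the list alone). The Sult3a1 average came from B6 livers, where its mean level went from 4.196 on the balanced to 6.519 on the enriched diet. In D2 livers its mean level went from 4.158 to 3.951, with 1 of 5 balanced and 0 of 5 enriched arrays above background. The female-biased median was 0.45 (adjusted p = 0.000388, but adjusted p = 0.259 with an estimated correlation). Of 19 interferon response genes 2 fell, Isg15 (-0.68) and Ifit3 (-0.61), and 11 fell adjusted over the list alone. The interferon median was -0.37 (adjusted p = 3.7e-10, but adjusted p = 0.223 with an estimated correlation). Of 16 genes of the unfolded protein response 1 fell, the chaperone calreticulin (Calr, -0.64; 5 adjusted over the list alone), at a list median of -0.18 (adjusted p = 8.47e-06, but adjusted p = 0.131 with an estimated correlation).

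Further large rises averaged over strains were Gucy2c (1.58), a membrane guanylate cyclase, Srgap3 (1.52) and the desmosomal Pkp1 (1.35). Further large falls were Clec2h (-2.14), Olfr166 (-1.90), Mmd2 (-1.75), the muscle myosin Myh2 (-1.68), the melanocortin receptor Mc1r (-1.66), Crxos (-1.60), Hsd3b4 (-1.40) and Ranbp3l (-1.25). Several of these averages came mostly from B6 livers: in B6 and D2 the change was 2.30 and 0.40 for Pkp1 (adjusted p = 0.0107 for the difference), -3.11 and -0.08 for Crxos (adjusted p = 0.0327), -2.70 and -0.11 for Hsd3b4 (adjusted p = 0.0852), -3.78 and -0.50 for Clec2h (adjusted p = 0.0722) and -2.78 and -0.53 for Mc1r (adjusted p = 0.268). It was 2.49 and 0.19 for Id4 and 1.38 and 0.12 for Abcc4. For Olfr166, Myh2 and Srgap3 another probe gave 0.14, 0.03 and 0.15, so those changes rest on 1 probe each. Gucy2c, Pkp1, Clec2h, Mmd2, Mc1r, Crxos, Hsd3b4 and Ranbp3l had 1 kept probe each, so no other probe could be compared. The other probes of Mt1 (0.72), Ifit3 (-0.57), Calr (-0.29) and Stab1 (0.11) had the same sign but did not pass, and neither did 1 of the other probes of Slc11a2 (-0.06). Of the 42 genes named for this comparison, 24 had all mice on the side of the mean change.

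In all, 469 genes passed at an adjusted p under 0.05 by limma, 256 higher and 213 lower, and 47 of them changed at least 2-fold. With slide as a block 302 passed, with scan day as a block 806, within scan day 2 28 and within scan day 3 898, and the deposited values without normalization between arrays gave 347, of which 24.8% were higher against 54.6% here. The fits within a day rest on single arrays in some groups: 1 B6 balanced, 1 B6 enriched and 1 D2 enriched array on day 2, and 1 D2 balanced array on day 3. The 41 named genes with a passing change kept their direction with either block, and 34 of them passed with slide, 41 with scan day, 7 within day 2 and 21 within day 3. With slide as a block Alas1 (adjusted p = 0.0573), Isg15 (adjusted p = 0.0781), Ifit3 (adjusted p = 0.185), Mt1 (adjusted p = 0.0688), Sult3a1 (adjusted p = 0.0768), Clec2h (adjusted p = 0.0573) and Hsd3b4 (adjusted p = 0.0887) did not pass. Blocked by slide, by scan day, within day 2 and within day 3, the change was 1.20, 1.21, 1.31 and 1.24 for Bmp6, 2.44, 2.39, 3.47 and 1.91 for Id1, 1.75, 1.71, 2.72 and 1.26 for Smad7, and 1.60, 1.55, 1.94 and 1.49 for Atoh8. For Hamp2 the values were 2.13, 2.05, 2.71 (adjusted p = 0.333) and 2.06, and for Hamp 1.85, 1.65, 2.34 and 1.59. In the same order the list medians were 1.67, 1.63, 2.33 and 1.38 for the title genes, 1.99, 1.85, 2.53 and 1.82 for hepcidin, 0.10, 0.07, 0.12 and 0.12 for BMP signalling, 0.12, 0.11, 0.11 and 0.18 for endothelial markers, and 0.31, 0.25, 0.17 and 0.35 for NRF2 targets. They were -0.31, -0.35, -0.41 and -0.39 for male-biased, 0.36, 0.53, 0.37 and 0.41 for female-biased, -0.33, -0.33, -0.61 and -0.34 for interferon, -0.14, -0.15, -0.21 and -0.17 for unfolded protein response, and 0.23, 0.25, 0.15 and 0.18 for cell cycle genes. They were 0.45, 0.38, 0.50 and 0.30 for metal-binding genes, -0.13, -0.10, -0.10 and -0.16 for heme synthesis, and 0.03, 0.04, -0.00 and 0.03 for iron transport.

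**Figure D2:**
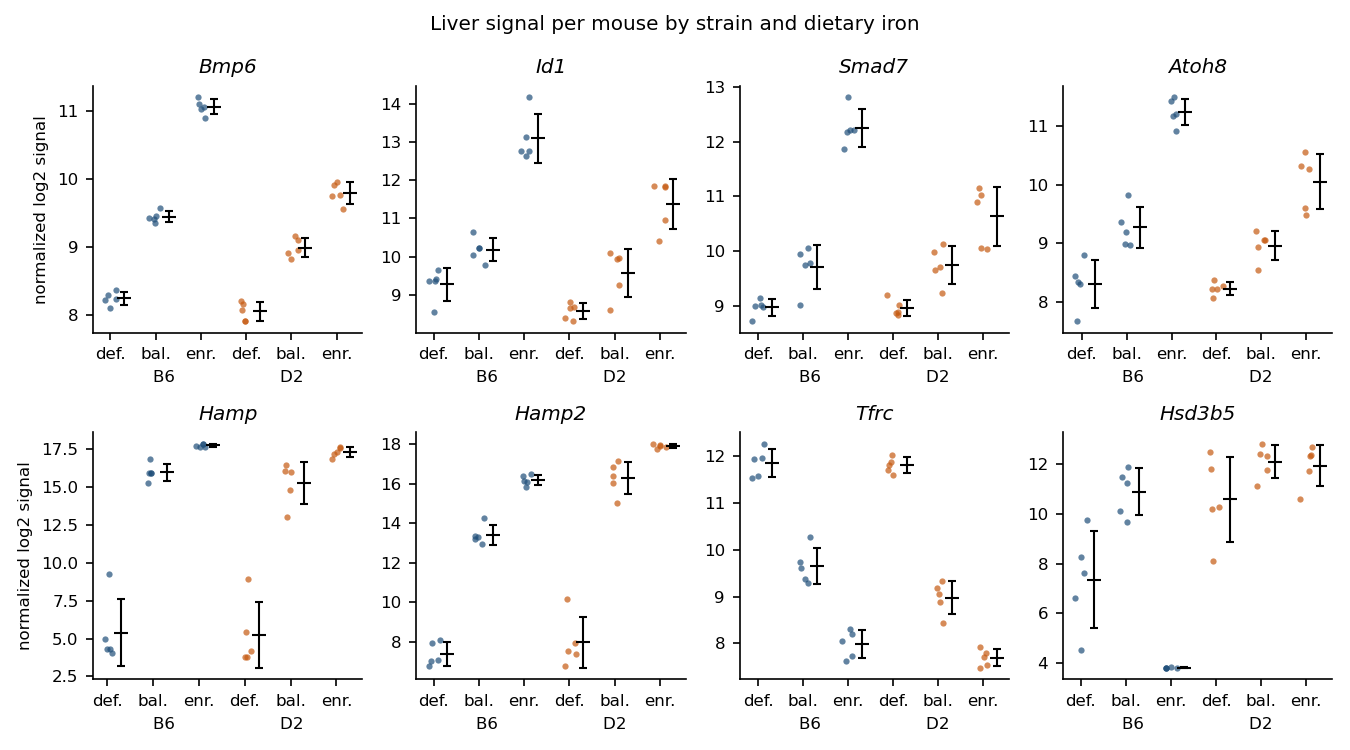
Normalized log2 level of 8 genes in each mouse (points), by strain and diet, with the group mean and SD (black, n = 5). Bmp6, Id1, Smad7 and Atoh8 have their highest means on the enriched and their lowest on the deficient diet in both strains, Tfrc the reverse, and Hsd3b5 has a low mean (3.81) in B6 enriched livers.

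Within strains, enrichment changed 1228 genes in B6 (697 higher, 531 lower) and 19 in D2 (15 higher, 4 lower). Bmp6, Id1, Atoh8, Akr1b8, Gucy2c, Srgap3 and Tfrc passed in D2 as well. Among the rest of the 19 in D2 were higher Apoa5, Cep55, Ces1e, Klrb1f, Pcp2 and Spata32 and lower Chchd6, Prss12 and Usf2, all named after their values were seen. The D2 count fell to 3 without D2 balanced mouse 2 or D2 enriched mouse 3, and each of 12 arrays moved it by over 1.5 times when left out. Smad7 rose by 2.55 in B6, and its D2 change was 0.89 (adjusted p = 0.185). Hamp2 changed by 2.78 in B6 and 1.62 in D2. With slide or scan day as a block, 1810 and 1701 genes passed in B6 and 17 and 24 in D2, and within scan days 2 and 3 there were 17 and 308 in B6 and 10 and 880 in D2. On day 2 both B6 groups and the D2 enriched group held 1 array, and on day 3 the D2 balanced group held 1. Without normalization between arrays 133 genes passed in D2, of which 6.77% were higher against 78.9% here, and cyclic loess gave 66.7%. Fitted on the D2 balanced and enriched arrays alone, 0 genes passed by limma, with 1149 at an unadjusted p under 0.05. The plain test without moderated variances, over all groups, gave 19 adjusted and 1241 unadjusted.

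The deficient against the balanced diet asked what follows when iron is withheld. Hamp fell by 10.30 (SE 0.604, adjusted p = 5.55e-12) and Hamp2 by 7.18 (SE 0.306, adjusted p = 8.32e-15), and both were lower in 10 of 10 deficient mice. The Hamp level in B6 livers went from 15.97 ± 0.57 (log2, SD, n = 5) to 5.38 ± 2.20. In D2 livers it went from 15.25 ± 1.39 to 5.24 ± 2.18, where 3 of 5 arrays were still well above background. Bmp6 fell by 1.07 (SE 0.059, adjusted p = 1.76e-12), by 1.20 in B6 and 0.94 in D2, and Tfrc rose by 2.51 (SE 0.128, adjusted p = 3.61e-13). Of 25 cholesterol synthesis genes 19 rose, of 24 fatty acid oxidation genes 11 rose, and of 19 interferon response genes 12 fell. These list calls were lost with an estimated correlation (adjusted p = 0.197, adjusted p = 0.0831 and adjusted p = 0.236).

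Of the title genes 4 of 4 fell (4 adjusted over the list alone), which is not independent evidence since the study chose them on these samples. Id1 fell by 0.96 (SE 0.219, adjusted p = 0.00665), Atoh8 by 0.84 (SE 0.142, adjusted p = 0.000455) and Smad7 by 0.76 (SE 0.153, adjusted p = 0.00231). Their list median was -0.90 (adjusted p = 1.97e-09, and adjusted p = 0.0042 with an estimated correlation), and that of the hepcidin genes, 2 of 2 lower (2 adjusted over the list alone), was -8.74 (adjusted p = 1.53e-12, and adjusted p = 0.000334 with an estimated correlation). Of 29 other genes of BMP signalling 3 rose and 1 fell (4 and 1 adjusted over the list alone), and the list as a whole did not differ (median 0.01, mean -0.01, adjusted p = 0.751). Id4 rose by 0.47, the BMP9 gene Gdf2 by 0.40 and the ubiquitin ligase Smurf1 by 0.26, and Smad9 fell by 0.43, with 0.12 (adjusted p = 0.309) at the other probe of Smurf1. Of 15 endothelial markers 4 rose and 1 fell, also adjusted over the list alone, at a median of 0.14 (adjusted p = 0.00875, but adjusted p = 0.371 with an estimated correlation). The receptor Flt1 (0.62), Emcn (0.38) and Pecam1 (0.31) rose and Oit3 fell (-0.25). For Flt1 2 of 4 other probes had the opposite sign, and the other probe of Oit3 gave -0.18 (adjusted p = 0.293).

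Of 28 genes of iron transport and storage 3 rose, 3 fell and 22 did not pass (5 higher and 3 lower adjusted over the list alone; list median 0.01, adjusted p = 0.207). Besides Tfrc, Slc11a2 rose by 0.55 (adjusted p = 8.22e-06, with -0.03 and 0.09 at its other probes). Ncoa4, which delivers ferritin to lysosomes, fell by 0.41, and the ferrireductase gene Steap3 fell by 0.31, with -0.04 (adjusted p = 0.921) at its other probe.

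Of 25 cholesterol synthesis genes 19 rose, 1 fell and 5 did not pass (20 and 1 adjusted over the list alone). Sqle rose by 2.21, Idi1 by 1.87, Cyp51 by 1.83, Hmgcs1 by 1.82, Nsdhl by 1.79, Fdps by 1.76 and Hsd17b7 by 1.33, with adjusted p between 1.54e-05 and 0.00405. The list median was 0.90 (adjusted p = 6.02e-19, but adjusted p = 0.197 with an estimated correlation). Of 24 genes of fatty acid oxidation 11 rose and 0 fell (15 and 0 adjusted over the list alone), at a median of 0.24 (adjusted p = 1.94e-13, but adjusted p = 0.0831 with an estimated correlation). They included Pdk4 (1.40), which restrains glucose oxidation, the peroxisomal Ehhadh (0.82), the fatty acid hydroxylase Cyp4a10 (0.44) and the dehydrogenase Acadl (0.39).

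Of 19 interferon response genes 12 fell (16 adjusted over the list alone), among them Ifit1 (-0.91), Isg15 (-0.82), Oasl1 (-0.78) and Ifit3 (-0.70). Their median was -0.56 (adjusted p = 5.58e-13, but adjusted p = 0.236 with an estimated correlation). Of 16 unfolded protein response genes 5 fell and 1 rose (7 and 1 adjusted over the list alone), at a median of -0.26 (adjusted p = 0.00029, but adjusted p = 0.27 with an estimated correlation). The falls included Sdf2l1 (-0.97), Herpud1 (-0.61), the disulfide isomerase Pdia4 (-0.32) and Edem1 (-0.28), all of endoplasmic reticulum protein quality control. Of 16 male-biased genes 5 fell and 1 rose (6 and 2 adjusted over the list alone), at a median of -0.38 (adjusted p = 0.001, but adjusted p = 0.371 with an estimated correlation). Hsd3b5 fell by 2.53, Selenbp2 by 0.69 and Nudt7 by 0.54. The interferon, unfolded protein response and male-biased medians were negative on the enriched diet too. Both comparisons use the same balanced mice, so a part that comes from these mice is not excluded. Cyp4a12a was higher by 0.34 at its brightest probe and lower at another (-0.88, adjusted p = 0.00738), so its direction is open.

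Further large rises were Ppp1r3g (1.88), a glycogen-targeting subunit of protein phosphatase, the adrenergic receptor Adra2a (1.75) and the lipid droplet gene Cidec (1.53). Further large falls were Ciart (-1.67), a repressor of the circadian clock, Nat8f5 (-1.67, adjusted p = 0.048), Hsd3b4 (-1.65), Clec2h (-1.59), Derl3 (-1.52), the P450 gene Cyp2c70 (-1.30) and Crxos (-1.20). The clock gene means of Arntl went from 10.55 to 11.25 in B6 and from 8.01 to 8.99 in D2 livers. Those of Dbp went from 12.34 to 11.20 and from 15.86 to 15.25. The hour of sampling is not given, so a different hour between the diet groups is not excluded for Ciart. Nor is it excluded for other genes of this comparison whose level varies with the hour. Of the 51 genes named for this comparison, 36 had all mice on the side of the mean change.

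In all, 1703 genes passed by limma, 819 higher and 884 lower, and 59 changed at least 2-fold. With slide or scan day as a block 1664 and 2193 passed, and within scan days 2 and 3 12 and 1519. The deposited values without normalization gave 979, of which 69.6% were higher against 48.1% here. Day 2 held 1 B6 balanced array and day 3 held 1 D2 balanced array, so the fits within a day rest on these. The 51 named genes kept their direction in these fits, and 41 of them passed with slide, 50 with scan day, 3 within day 2 and 15 within day 3. Besides Id1, those lost with slide were Adra2a, Clec2h, Crxos, Cyp2c70, Cyp4a12a, Gdf2, Nat8f5, Pdia4 and Smad9, with adjusted p between 0.0605 and 0.169, and Nat8f5 was also lost with scan day (adjusted p = 0.0552). In the order slide, scan day, day 2 and day 3, the change was -1.01, -1.07, -0.95 and -1.18 for Bmp6, -0.81 (adjusted p = 0.083), -0.96, -0.51 (adjusted p = 0.516) and -1.49 for Id1, -0.71, -0.76, -0.32 (adjusted p = 0.368) and -1.05 for Smad7, and -0.67, -0.84, -0.77 (adjusted p = 0.15) and -0.82 (adjusted p = 0.093) for Atoh8. For Hamp it was -9.94, -10.20, -11.10 and -9.38 and for Hamp2 -6.92, -7.14, -7.47 and -6.46. List medians in that order were -0.76, -0.90, -0.64 and -1.11 for the title genes, -8.43, -8.67, -9.28 and -7.92 for hepcidin, 0.91, 0.92, 1.01 and 0.82 for cholesterol synthesis, and 0.22, 0.24, 0.19 and 0.26 for fatty acid oxidation. They were -0.54, -0.58, -0.69 and -0.33 for interferon, -0.29, -0.25, -0.03 and -0.34 for unfolded protein response, -0.31, -0.41, -0.34 and -0.20 for male-biased genes, and 0.17, 0.14, 0.06 and 0.12 for endothelial markers.

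Within strains, deficiency changed 378 genes in B6 (234 higher, 144 lower) and 986 in D2 (376 higher, 610 lower). These counts fell to 180 without B6 deficient mouse 4 and to 505 without D2 balanced mouse 5, and to 167 and 563 without the 3 balanced arrays least similar to their own group. The blocks gave 65 (slide) and 403 (scan day) in B6 and 1083 and 1343 in D2, and within scan days 2 and 3 there were 12 and 8 in B6 and 3 and 1552 in D2. The B6 value of day 2 and the D2 value of day 3 each rest on 1 balanced array. Without normalization between arrays the higher share in B6 was 88.0% against 61.9%. Under that setting the median of all genes was 0.10 for deficiency in B6, -0.16 for enrichment in D2, -0.17 for D2 against B6 and -0.22 for the difference between strains of the enrichment effect, against 0.01, -0.01, -0.01 and -0.03 here.

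Over both diet contrasts 2471 genes passed limma's F test. Both single contrasts passed for 163 genes, of which 118 moved the same way and 45 in opposite ways. The opposite group held Bmp6, Id1, Smad7, Atoh8, Hamp2, Tfrc, Slc11a2, Slc40a1, Gucy2c and Smad9. Independent lists of these sizes would share 9.95 genes higher in both, 8.93 lower in both, 10.7 higher on the enriched and lower on the deficient diet, and 8.28 the reverse, where 49, 69, 34 and 11 were found. Both contrasts share the balanced mice, which alone makes their changes covary: the covariance across genes was 0.0188, against a mean of 0.0109 in 20 simulations without effects, while the correlation was 0.393 against 0.496. When the balanced mice were divided between the contrasts, the median over 40 divisions was 38 shared genes, 21.5 opposite and 18 in the same direction, with a covariance of 0.0061 and a correlation of 0.0981. With fewer balanced mice per contrast the lists themselves shrank, to medians of 223.5 genes for enrichment and 920.5 for deficiency, against 469 and 1703. With slide or scan day as a block the F test passed 1961 and 3228 genes and 23 and 53 were opposite, and within scan days 2 and 3 these were 56 and 1252, and 2 and 14.

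D2 against B6, averaged over diets, asked how the strains differ in liver expression. Bmp6 was lower in D2 livers by 0.64 (adjusted p = 1.04e-11), as were Id1 (-1.01, adjusted p = 2.82e-05), Atoh8 (-0.53) and Smad7 (-0.53, adjusted p = 0.000781, lower in 11 of 15 mice). For Smad7 and Atoh8 the enriched diet carried this average, and the Bmp6 difference was also largest there. Bmp6 stood at 8.99 in D2 and 9.45 in B6 livers on the balanced diet, at 8.06 and 8.25 on the deficient and at 9.79 and 11.06 on the enriched diet. Smad7 stood at 9.74 in D2 and 9.71 in B6 livers on the balanced diet and at 8.96 in both on the deficient diet, against 10.63 and 12.25 on the enriched diet. Atoh8 stood at 8.96 and 9.27, 8.23 and 8.32, and 10.05 and 11.24 on the same diets. Hamp2 was higher by 1.72 (adjusted p = 1.61e-06), and Hamp did not pass (-0.44, adjusted p = 0.488). In D2 livers 19 of 19 interferon response, 13 of 16 male-biased and 20 of 25 cholesterol synthesis genes were higher, and 14 of 15 macrophage markers, 13 of 15 endothelial markers and 14 of 23 NRF2 targets were lower. These list calls were lost with an estimated correlation (adjusted p = 0.601 for cholesterol synthesis and adjusted p = 0.374 for the others). The largest differences were those of Ntrk2 (6.80), a neurotrophin receptor with a mean level of 11.92 in balanced D2 and 5.04 in balanced B6 livers (log2, n = 5), and Nalp12 (-6.38).

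Averaged over diets, the title genes, chosen by the study on these samples and so not independent evidence, were lower in 4 of 4 cases (4 adjusted over the list alone), at a median of -0.58 (adjusted p = 0.0278, but adjusted p = 0.374 with an estimated correlation). Of the hepcidin genes 1 of 2 was higher, also adjusted over the list alone (median 0.64, adjusted p = 0.564). Of 28 iron transport and storage genes 10 were higher and 8 lower (list median -0.02, adjusted p = 0.953). Steap2 (-0.97) and the heme-degrading Hmox1 (-0.83) were lower, and Steap3 (0.59, with 0.21 at another probe that did not pass) was higher. Of 15 macrophage and Kupffer cell markers 14 were lower and 1 higher, among them Adgre1 (-0.94), C1qc (-0.91), Cd14 (-0.88) and Cd5l (-0.77). The macrophage median was -0.54 (adjusted p = 1.59e-05, but adjusted p = 0.374 with an estimated correlation). Of 15 sinusoidal endothelial markers 13 were lower, including Lyve1 (-2.24), Oit3 (-0.49), Gpr182 (-0.45) and Cdh5 (-0.42). The endothelial median was -0.26 (adjusted p = 0.000236, but adjusted p = 0.374 with an estimated correlation).

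All 19 interferon response genes were higher in D2 livers, among them Ifit1 (2.10), Mx2 (2.09), Isg15 (1.87) and Ifit3 (1.65). Their median was 1.20 (adjusted p = 5.37e-10, but adjusted p = 0.374 with an estimated correlation). Of 16 male-biased genes 13 were higher and 1 lower (14 and 1 adjusted over the list alone), at a median of 0.83 (adjusted p = 0.000166, but adjusted p = 0.374 with an estimated correlation), with Hsd3b5 (4.2), Nudt7 (1.78), Cyp2u1 (1.44) and Mup5 (1.25). The enriched B6 group weighed on these averages: Hsd3b5 stood at 12.11 in D2 and 10.90 in B6 livers on the balanced diet and at 11.96 and 3.81, near the floor, on the enriched diet, and Mup5 at 17.51 and 17.14 and at 17.64 and 15.37. Of 25 cholesterol synthesis genes 20 were higher and 1 lower (21 and 1 adjusted over the list alone), at a median of 0.89 (adjusted p = 0.000343, but adjusted p = 0.601 with an estimated correlation). Examples are Msmo1 (1.92), the sterol carrier Stard4 (1.34) and Tm7sf2 (0.33). Of 18 acute phase genes 13 were higher and 2 lower, at a median of 0.54 (adjusted p = 0.00217, but adjusted p = 0.374 with an estimated correlation), with serum amyloid P (Apcs, 2.73), fibrinogen alpha (Fga, 1.59), Saa4 (1.03) and Crp (0.74). Of 23 NRF2 targets 14 were lower and 2 higher, at a median of -0.29 (adjusted p = 0.00142, but adjusted p = 0.374 with an estimated correlation), with Abcc4 (-1.74), Htatip2 (-0.93), Gclm (-0.76) and Akr1b8 (-0.53). The enriched diet carried the Akr1b8 average, with 11.03 in D2 and 12.28 in B6 livers there. On the balanced diet these were 10.14 and 10.23, and on the deficient diet 10.12 and 10.37.

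Of 18 circadian clock genes 10 were higher and 5 lower. Dbp (4.18) and Per3 (3.89), which peak in the evening in mouse liver, were higher, and the activators Arntl (-2.73) and Clock (-0.79), which peak in the morning, were lower. Since the list moved both ways, its median of 0.72 was not called (adjusted p = 0.136). The hour of sampling was not given for either strain. A different hour is thus not excluded for other genes of the strain comparison whose level varies with the hour. For lists of the strain comparison without another count, adjustment over the list alone gave the same counts.

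**Figure D3:**
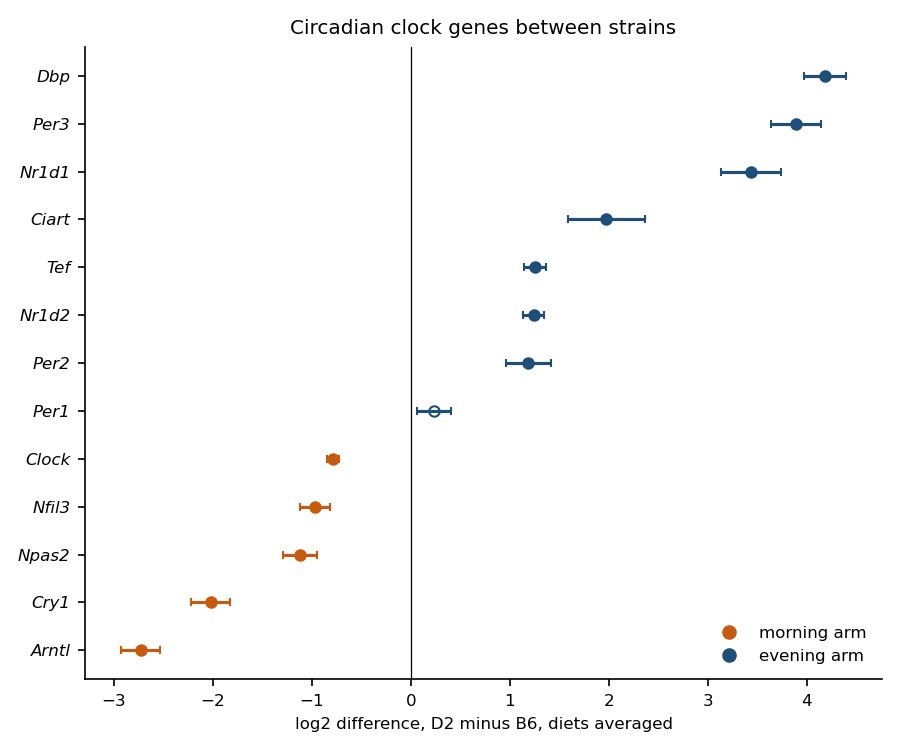
Difference D2 minus B6, averaged over diets (log2, bars give the SE), of 13 circadian clock genes grouped by the time of day at which they peak in mouse liver. Filled points passed at an adjusted p under 0.05; the 5 genes of the morning arm were lower in D2 livers, and 7 of the 8 genes of the evening arm were higher.

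Of 6 genes with allele differences known between these strains 3 were higher and 1 lower (list median 0.49, adjusted p = 0.211). Alad, which D2 mice carry in several copies, was higher by 1.60 (adjusted p = 7.56e-21), and Glo1 (0.95) was higher too. The complement gene Hc, inactivated in D2, was lower by 1.28. Nnt, partly deleted in a B6 substrain, was higher by 1.64, with 1.53, 1.53 and -0.16 at its other probes. Further genes with the largest differences were Rassf4 (5.66), the protease genes Ctse (5.50) and Corin (5.19), the protease inhibitor Serpina3a (4.55), Gpr12 (4.37), Dct (4.34), Tnfrsf14 (4.27) and Tmc5 (4.2), all higher in D2 livers. The folate receptor Folr2 (-4.74), the cell cycle inhibitor Cdkn1a (-4.62), Zfp874a (-4.55), the peptidase Mme (-4.55), Nnmt (-4.52), Tceanc2 (-4.39), Fin15 (-4.17), Pcdh17 (-3.99) and Lpin1 (-3.80) were lower. The other probe of Pcdh17 gave -0.33 (adjusted p = 0.182), that of Nalp12 -1.56 and those of Ntrk2 6.41 and 0.38. Probes can also differ between strains through sequence variants under them, and the size of a difference is uncertain where the lower strain is dim. Serpina3a, Tmc5 and Tnfrsf14 in B6 livers and Pcdh17, Fin15 and Mme in D2 livers were above background on fewer than 5 of 5 arrays in at least 2 diet groups.

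In all, 10563 genes differed by limma, 5460 higher and 5103 lower in D2, and 1299 of them at least 2-fold. With slide or scan day as a block 11397 and 11145 passed, and within scan days 2 and 3 6140 and 8196. The deposited values without normalization gave 11062, of which 28.6% were higher against 51.7% here. All 64 named genes with a passing difference kept both direction and call with either block. On day 2 the B6 balanced, B6 enriched and D2 enriched groups and on day 3 the D2 balanced group held 1 array each. In the order slide, scan day, day 2 and day 3, list medians were -0.58, -0.60, -0.50 and -0.54 for the title genes, 1.18, 1.18, 1.19 and 0.97 for interferon, -0.56, -0.53, -0.70 and -0.41 for macrophage markers, -0.23, -0.25, -0.31 and -0.20 for endothelial markers, and 0.82, 0.87, 0.89 and 0.96 for male-biased genes. They were 0.84, 0.87, 0.62 and 0.91 for cholesterol synthesis, 0.52, 0.49, 0.52 and 0.40 for acute phase genes and -0.24, -0.26, -0.42 and -0.26 for NRF2 targets.

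The difference between strains of the enrichment effect (D2 minus B6) asked whether the strains respond alike to iron loading. Bmp6 and Smad7 changed less in D2 than in B6 livers: Bmp6 by 0.80 against 1.61 (difference -0.82, adjusted p = 0.000595) and Smad7 by 0.89 against 2.55 (difference -1.66, adjusted p = 0.00563). Of 16 male-biased genes 10 fell in B6 livers (12 adjusted over the list alone), at a median of -0.64 (adjusted p = 1.93e-16, and adjusted p = 0.0122 with an estimated correlation), while their D2 median was 0.03 (adjusted p = 0.364). Of 16 female-biased genes 6 rose in B6 livers (8 adjusted over the list alone), at a median of 1.06 (adjusted p = 1.3e-07, but adjusted p = 0.17 with an estimated correlation), and their D2 median was -0.21 (adjusted p = 0.221). Hsd3b5 changed by -7.09 in B6 and -0.15 in D2 livers (difference 6.94, adjusted p = 0.000602), and in B6 enriched livers 2 of 5 arrays stood above background, so the floor limits the size of its fall. Cyp2b10, a xenobiotic P450 gene, rose by 3.04 in B6 livers and its D2 change was -0.35 (difference -3.40, adjusted p = 0.0179).

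Of the title genes, which the study chose on these samples and which are not independent evidence, 2 of 4 had a smaller rise in D2 (4 adjusted over the list alone). The differences of Id1 (-1.10, adjusted p = 0.278) and Atoh8 (-0.88, adjusted p = 0.144) did not pass. The list median was -0.99 (adjusted p = 2.35e-07, and adjusted p = 0.0153 with an estimated correlation). Neither hepcidin gene passed: Hamp differed by 0.28 (adjusted p = 0.973) and Hamp2 by -1.16 (adjusted p = 0.48). Of 29 other BMP signalling genes 2 differed, Id4 (-2.30, adjusted p = 7.13e-05) and the decoy receptor Bambi (-1.07), and the list did not (median -0.09, adjusted p = 0.322; 1 higher and 2 lower adjusted over the list alone). Id4 rose by 2.49 in B6 and its D2 change was 0.19.

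Of 16 male-biased genes 8 differed, all with a positive difference (12 adjusted over the list alone), at a median of 0.75 (adjusted p = 3.09e-16, and adjusted p = 0.0153 with an estimated correlation). Slco1a1 (3.76), Mup5 (1.90) and Nudt7 (1.47) were examples. Of 16 female-biased genes 2 differed, Sult3a1 (-2.53, adjusted p = 0.0243) and Cyp2b13 (-4.29, adjusted p = 0.0388), and 5 adjusted over the list alone. The female-biased median was -1.07 (adjusted p = 7.8e-08, but adjusted p = 0.173 with an estimated correlation). Sult3a1 was not above background on any D2 enriched array, so its level in B6 enriched livers was at least 5.33-fold higher. Of 23 NRF2 targets 3 differed (1 higher and 9 lower adjusted over the list alone), Akr1b8 (-1.15), Abcc4 (-1.25) and Gsta4 (-1.08), at a median of -0.32 (adjusted p = 4.23e-05, but adjusted p = 0.175 with an estimated correlation). Of 28 xenobiotic P450 genes 1 had a positive and 3 a negative difference, with Cyp2c55 (-1.10) and Cyp2d22 (0.48) besides the Cyp2b genes (4 and 9 adjusted over the list alone; list median -0.30, adjusted p = 0.134). Cyp2d22 had -0.07 and 0.16 at its other probes, and the other probe of Bmp6 gave -0.72 (adjusted p = 0.0513). Further genes with the smallest adjusted p were Mcm10 (1.82, from -1.92 in B6 and -0.09 in D2), the steroid reductase Srd5a1 (2.12, from -2.07 and 0.05) and Chpf (-1.18).

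In all, 234 genes passed by limma for this difference, 90 positive and 144 negative, and 200 passed the F test over both interaction contrasts. With slide or scan day as a block 259 and 365 passed (133 and 294 for the F test), and within scan days 2 and 3 16 and 465 (12 and 234). Without normalization between arrays 894 passed, of which 5.59% were positive against 38.5% here. In the order slide, scan day, day 2 and day 3, list medians were -1.02, -0.99, -1.27 and -1.20 for the title genes, 0.79, 0.78, 0.87 and 0.85 for male-biased genes, -1.25, -1.29, -1.97 and -0.95 for female-biased genes, -0.37, -0.31, -0.23 and -0.42 for NRF2 targets and -0.38, -0.36, -0.75 and -0.47 for P450 genes. All 19 named genes kept their direction with either block, and 15 with slide, 19 with scan day, 0 of 18 within day 2 (limma on groups of which 3 held 1 array) and 8 within day 3 (with 1 D2 balanced array) also passed. With slide Sult3a1 (adjusted p = 0.0991), Cyp2b13 (adjusted p = 0.0573), Gsta4 (adjusted p = 0.0719) and Cyp2d22 (adjusted p = 0.086) did not pass.

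**Figure D4:**
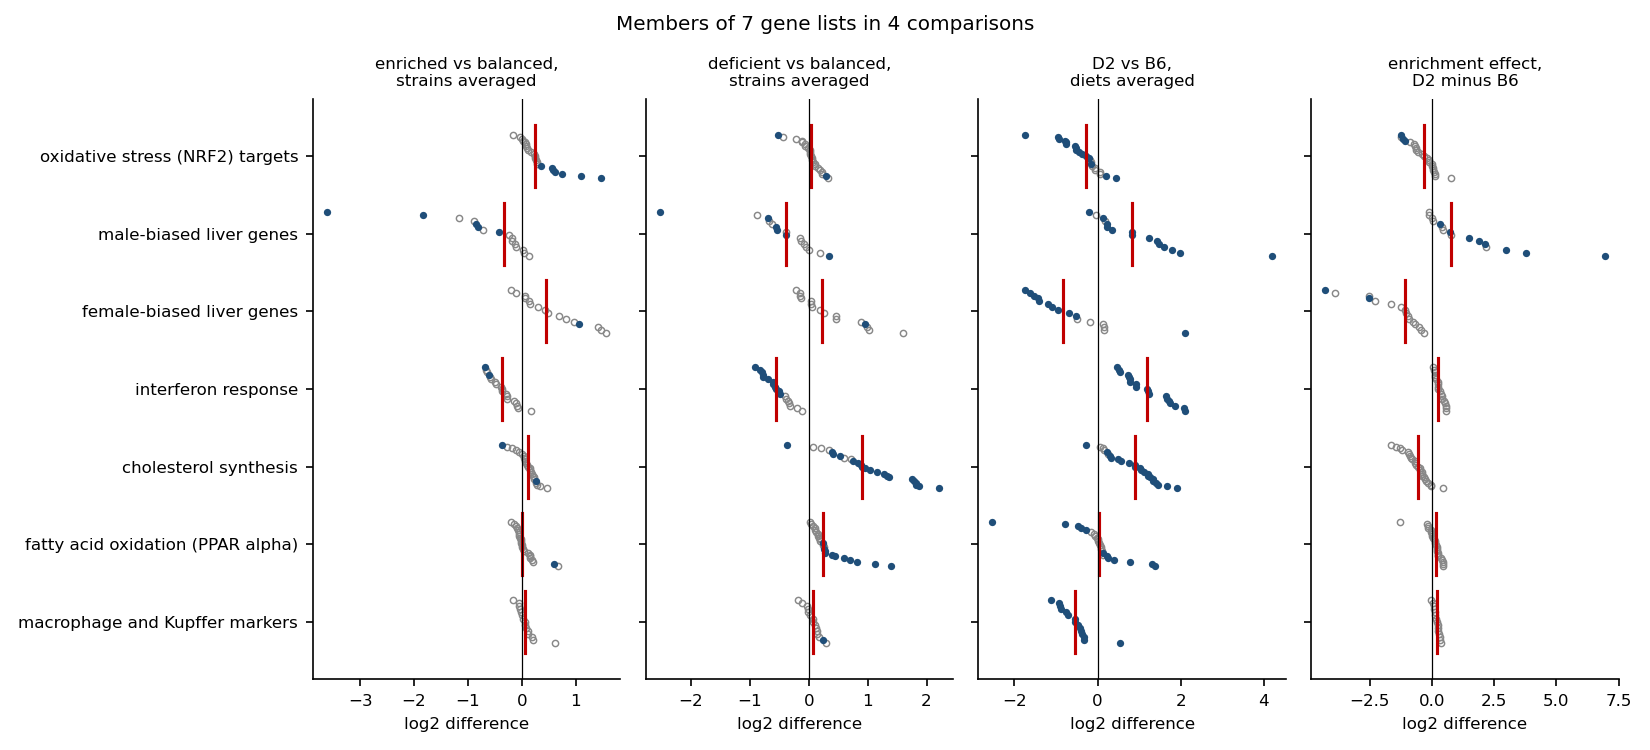
Changes (log2) of the members of 7 gene lists in 4 comparisons: enriched against balanced, deficient against balanced, D2 against B6, and the difference between strains of the enrichment effect. Each point is 1 gene, filled where it passed at an adjusted p under 0.05, and red lines are list medians; male-biased genes have a median of 0.75 for the difference between strains.

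The difference between strains of the deficiency effect (D2 minus B6) asked whether the strains respond alike to iron withdrawal. By limma 4 genes passed, all with a more negative change in D2: Plscr2 (-0.70, adjusted p = 0.0109, from 0.28 in B6 and -0.42 in D2), Slc16a11 (-0.84, adjusted p = 0.0156, from 0.30 and -0.54), Kazald1 (-0.59, adjusted p = 0.0372, from -0.02 and -0.61) and a clone without a gene name (-1.40, adjusted p = 0.0372). Of the title genes 0 of 4 passed, also adjusted over the list alone: Bmp6 differed by 0.26 (adjusted p = 0.672), Atoh8 by 0.23, Id1 by -0.08 and Smad7 by -0.04 (list median 0.09, adjusted p = 0.339). Neither hepcidin gene passed, with 0.58 for Hamp and -2.29 for Hamp2 (adjusted p = 0.371; list median -0.85, adjusted p = 0.211). Camera passed 8 of the 36 lists for this difference, while fry and camera with an estimated correlation passed 0 each. Of these lists the male-biased one is given under the other observations. At an unadjusted p under 0.05 there were 1500 genes by limma, and the plain test without moderated variances gave 3 adjusted and 1578 unadjusted. With scan day as a block 9 genes passed, with slide 0 (limma, 1711 unadjusted), and within scan days 2 and 3 5 and 266, which rest on 1 B6 balanced and 1 D2 balanced array respectively.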

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

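The tests on clock genes, on sex-biased genes and on sequence variants were chosen only after the result was seen, while the comparison of signal over background between strains and the regroupings of the mice were fixed earlier. Single arrays far from the other 4 of their group were looked for in 698 combinations of named gene and group. The measure was the gap of the highest or lowest array to its nearest neighbour, divided by the group's range. It passed the critical value (0.71 for 5 arrays) in 47 combinations, and chance gives about 1 in 20. That rate does not hold where the other arrays lay at the floor, since any small excess then passes.

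In B6 balanced livers the gap was 0.808 for Cyp4a12a (mouse 1, high), 0.718 for Smad7 (mouse 1, low), 0.841 for Oasl1 (mouse 4, low), 0.883 for Sdf2l1 (mouse 5, high) and 1 for Serpina3a (mouse 5, high, with the other 4 at the floor). In B6 enriched livers it was 0.737 for Alas1 (mouse 1, low), 0.769 for Cyp2c55 (mouse 1, high), 0.767 for Nnmt (mouse 3, high), 0.722 for Cyp2b13 (mouse 4, low), 0.722 for Adgre1 (mouse 5, high), 0.776 for Cyp2u1 (mouse 5, high) and 0.785 for Mt1 (mouse 5, low). It was 1 for Hsd3b5 (mouse 4, high) and for Serpina3a (mouse 1, high), where the other arrays lay at the floor. In B6 deficient livers it was 0.821 for Hamp (mouse 1, high), 0.845 for Ctse (mouse 1, high), 0.735 for Id1 (mouse 1, low), 0.844 for Apcs (mouse 3, high), 0.845 for Pdia4 (mouse 3, high), 0.799 for Crxos (mouse 3, low) and 0.823 for Mup5 (mouse 3, low). It was 0.711 for Rassf4 (mouse 4, low), 1 for Serpina3a (mouse 4, high, with the others at the floor) and 0.774 for Ifit1 (mouse 5, low).

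In D2 balanced livers it was 0.721 for Akr1b8, 0.787 for Nalp12, 0.775 for Ncoa4 and 0.842 for Pdk4 (mouse 2, all high), 0.783 for Tmc5 (mouse 3, high), 0.726 for Msmo1 (mouse 4, high) and 0.834 for Cyp2c70 (mouse 5, low). In D2 enriched livers it was 0.727 for Ranbp3l (mouse 1, low), 0.733 for Ntrk2 (mouse 2, low), 0.764 for Serpina3a (mouse 4, high), 0.835 for Lpin1 (mouse 5, high), 0.74 for Srgap3 (mouse 5, low) and 1 for Sult3a1 (mouse 5, high, with the others at the floor). In D2 deficient livers it was 0.937 for Cyp4a10, 0.729 for Hsd17b7 (both mouse 2, high), 0.775 for Ifit1 and 0.725 for Oasl1 (both mouse 2, low), 0.758 for Cd14 (mouse 3, high), 0.912 for Emcn (mouse 4, low) and 0.746 for Tmc5 (mouse 4, high). In mouse 5 of that group it was 0.835 for Saa4 (high), 0.827 for Ehhadh (low) and 0.839 for Smurf1 (low). No array had more than 4 of these gaps.

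The enrichment effect differed between the strains by limma's interaction test (D2 minus B6, log2) for Hsd3b5 (6.94), Slco1a1 (3.76), Srd5a1 (2.12), Mup5 (1.90), Mcm10 (1.82), Nudt7 (1.47) and Cyp2d22 (0.48), with a positive difference. It was negative for Bmp6 (-0.82), Bambi (-1.07), Gsta4 (-1.08), Cyp2c55 (-1.10), Akr1b8 (-1.15), Chpf (-1.18), Abcc4 (-1.25), Smad7 (-1.66), Id4 (-2.30), Sult3a1 (-2.53), Cyp2b10 (-3.40) and Cyp2b13 (-4.29). The deficiency effect differed for Plscr2 (-0.70), Slc16a11 (-0.84) and Kazald1 (-0.59).

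Male-biased genes fell with enrichment more in B6 than in D2 livers (8 of 16 differed; adjusted p = 0.0153 with an estimated correlation), while of 16 female-biased genes 2 differed the other way (adjusted p = 0.173 with an estimated correlation). Mixed-up sexes are argued against by the Y-linked genes, whose median change with enrichment in B6 livers was 0.059. A batch effect of the scan day is argued against by the male-biased median difference between strains, 0.78 with scan day as a block against 0.75 without. The hepatocyte markers had a median change of 0.0128 and so gave no sign of a lower share of hepatocytes. A list median after quantile normalization cannot exclude such a lower share. A strain difference in the response itself remains open, and its cause was not tested. A different hour of sampling between the B6 groups is not excluded either, since the hour is not given. With enrichment the mean of Arntl went from 10.55 to 11.56 in B6 and from 8.01 to 8.18 in D2 livers. That of Dbp went from 12.34 (SD 1.19) to 10.73 and from 15.86 to 15.70, while Clock went from 11.85 to 11.95 in B6 livers.

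Of 18 clock genes 15 differed between the strains. Other probes argue against sequence variants for the clock genes they cover, since 83.3% of them (10 of 12) had the same direction. Arntl, Dbp and Per3 had 1 kept probe each, so this check does not reach them. A scan day effect is argued against by the 15 genes, all of which kept direction and call with scan day as a block. The 5 morning genes had a median of -1.12 and the 8 evening genes one of 1.62, a gap of 2.73, which a different hour of sampling could give. A difference of clock phase between the strains could give it too, and since the hour is not given, both remain open.

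Of the probes well above background on all arrays of 1 strain and on no array of the other, 45 were silent in D2 livers and 15 in B6 livers (exact binomial test, two-sided p = 0.000135). The test counts probes as independent, while all were read on the same arrays, so its p does not measure variation between mice. Sequence variants under the probes may contribute. Where genes silent in D2 had other probes (41 probes of 24 genes), these had a median difference of -0.37 (0.43 in size), against -2.31 at the silent probes. For genes silent in B6 the medians were 0.42 at the other probes and 1.78 at the silent ones. The silent probes were chosen for their strain difference, so a smaller difference at other probes can arise in both strains whatever the cause. These medians therefore cannot tell whether sequence variants account for the excess in D2. A lower signal on the D2 arrays may contribute as well, since their share of probes well above background was lower by 2.73 points (-2.73, from 71.5% to 68.8%), which lies within the SD of several groups. Real absence of expression in D2 livers remains open, and 12 of the 41 other probes were lower by at least 1.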

How the results depend on the processing

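The filter at 2.6 SD, the filter on either strain, the fits within a scan day, the fit without 3 balanced arrays and the blocked tests of gene lists were chosen only after the data were seen, and the other settings beforehand. The title and hepcidin genes of the averaged diet comparisons are given singly and are not in the next counts. The other named genes kept direction and side of the threshold in 2304 of the gene and setting combinations fixed beforehand. They lost the call in 96, gained it in 4 (all by the plain test without adjustment) and reversed in 1. That reversal was Cyp4a12a on the deficient diet (-0.27 as the mean of its probes, against 0.34), whose probes disagree in sign. In the settings added later 691 were kept and 197 lost the call, and with 1 array left out 5108 were kept, 231 lost and 1 gained (the deficiency difference of Hamp2 without D2 deficient mouse 1). Gene lists kept their call in 102, 85 and 1320 combinations, lost it in 25, 2 and 0 and gained it in 5, 1 and 0. With an estimated correlation 8 of the 54 list calls of camera held. The causes of the changes were not tested except where fewer arrays or a stricter rule brings them.

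The numbers of passing genes with the settings of the report were 469 for enrichment (1228 in B6, 19 in D2), 1703 for deficiency (378 in B6, 986 in D2), 10563 between strains, 234 and 4 for the strain difference of the enrichment and of the deficiency effect, 2471 for the F test over diets, 200 for the F test of interaction and 45 opposite genes. Counts more than 1.5 times off these were as follows. Cyclic loess gave 7 for the difference of deficiency effects. The value table without normalization gave 979 for deficiency, 713 for enrichment in B6, 133 for enrichment in D2, 452 for deficiency in D2, 894 for the difference of enrichment effects, 456 for the interaction F test and 27 opposite genes. Slide as a block gave 302 for enrichment, 65 for deficiency in B6, 133 for the interaction F test and 23 opposite genes. It gave 0 for the difference of deficiency effects (limma, 1711 unadjusted), where the plain test without a block gave 3. With slide, Id1 on the deficient diet no longer passed (-0.81). Scan day as a block gave 806 for enrichment and 365 and 9 for the differences of effects. Fits of the compared groups alone, which hold fewer arrays, gave 328 and 0 for enrichment in B6 and D2 and 24 and 296 for deficiency. The 0 in D2 is by limma, with 1149 unadjusted, where the plain test over all groups gave 19. Trend and robust variances gave 2 for the difference of deficiency effects and 316 for the interaction F test. Array weights gave 789 for enrichment, 69 for enrichment in D2, 355 for the difference of enrichment effects and 394 for the interaction F test. The plain test gave 313 for the interaction F test. Without adjustment it gave 2998 for enrichment, 4527 for deficiency, 3841, 1241, 2714 and 3841 for enrichment in B6 and D2 and deficiency in B6 and D2, 2567 and 1578 for the differences of effects, 5312 and 2660 for the F tests and 218 opposite genes. A minimum of 1.5-fold, a stricter rule, gave 146, 293, 498, 180, 322, 3219, 154, 419 and 10 for enrichment, deficiency, enrichment in B6, deficiency in B6, deficiency in D2, strain, the difference of enrichment effects, the diet F test and opposite genes.

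Within scan day 2, with 11 arrays and 1 in each of the B6 balanced, B6 enriched and D2 enriched groups, the counts were 28, 12, 17, 10, 12, 3 and 6140 for enrichment, deficiency, enrichment in B6 and D2, deficiency in B6 and D2, and strain, then 16 for the difference of enrichment effects, 56 and 12 for the F tests and 2 opposite genes. There Hamp2 did not pass on the enriched diet (2.71), nor did Atoh8 (-0.77), Id1 (-0.51) and Smad7 (-0.32) on the deficient diet. Within scan day 3, with 14 arrays and 1 in the D2 balanced group (mouse 5, array weight 0.269), they were 898 for enrichment, 308 and 880 for enrichment in B6 and D2, 8 and 1552 for deficiency in B6 and D2, 465 and 266 for the differences of effects, 1252 for the diet F test and 14 opposite genes, so these counts say little on stability, and Atoh8 did not pass on the deficient diet (-0.82). Without the balanced arrays least similar to their own group (B6 mice 3 and 4, D2 mouse 5) they were 1058 for deficiency, 654 for enrichment in B6, 167 and 563 for deficiency in B6 and D2, 80 and 0 for the differences of effects and 28 opposite genes. The 0 is by limma, with 1373 unadjusted, where the plain test on all arrays gave 3. Hamp passed on the enriched diet with normexp (1.89, adjusted p = 0.00548), with the compared groups alone (1.90, adjusted p = 0.0037), array weights (2.06, adjusted p = 0.035) and the plain test without adjustment (1.90).

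Leaving out 1 array at a time, counts ran from 336 to 506 for enrichment, 1393 to 1739 for deficiency, 862 to 1394 for enrichment in B6, 3 to 19 for enrichment in D2, 180 to 429 for deficiency in B6, 505 to 1079 for deficiency in D2, 10254 to 10777 for strain, 139 to 289 and 1 to 7 for the differences of effects, 2141 to 2576 and 121 to 245 for the F tests and 31 to 45 for opposite genes. The Hamp change on the enriched diet ran from 1.62 to 2.05 and passed without B6 deficient mouse 1 (1.90, adjusted p = 0.0319) or D2 deficient mouse 1 (1.90, adjusted p = 0.0396). Enrichment in D2 (19) gave 12 without B6 enriched mouse 1 or 5, B6 deficient mouse 4 or 5 or D2 balanced mouse 1, 3 without D2 balanced mouse 2, 11 without mouse 3 and 10 without mouse 4 of that group, and 11, 8, 3 and 11 without D2 enriched mouse 1, 2, 3 and 4. Deficiency in B6 (378) gave 224 without B6 balanced mouse 5, and 224, 180 and 228 without B6 deficient mouse 3, 4 and 5. Deficiency in D2 (986) gave 505 without D2 balanced mouse 5, and 535 and 544 without D2 deficient mouse 1 and 3. The difference of enrichment effects (234) gave 144 and 153 without D2 balanced mouse 1 and 4, and 139 and 154 without D2 enriched mouse 2 and 3. The difference of deficiency effects (4) gave 7 without B6 balanced mouse 2, 1 without D2 balanced mouse 3, and 2 without B6 balanced mouse 3, 4 or 5, B6 enriched mouse 5, B6 deficient mouse 2, D2 balanced mouse 2 or 4, or D2 deficient mouse 2, 3 or 4. The interaction F test (200) gave 128 without B6 enriched mouse 5, and 121, 128 and 127 without D2 enriched mouse 2, 3 and 4. Signal over background limits Hamp on the deficient diet, where 3 of 5 D2 arrays stood above it, and Hsd3b5 in B6 enriched livers, where 2 of 5 did. It also limits Clec2h (3 of 5 in B6 enriched and in D2 deficient livers) and Ranbp3l (3 of 5 in B6 enriched). The same holds for Sult3a1 (3 of 5 in B6 balanced, 1 of 5 in D2 balanced) and Adra2a (3 of 5 in D2 balanced).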

Other observations

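Of the tests here, those of gene lists with slide as a block were chosen only after the result was seen. On the enriched diet the iron-sulfur assembly gene Iscu fell (-0.18), 1 of 13 genes of that list (median -0.06, adjusted p = 0.0312, but adjusted p = 0.326 with an estimated correlation, and 0.0607 with slide as a block). The 30 respiratory chain genes had a median of -0.03 (adjusted p = 0.00387, but adjusted p = 0.331 with an estimated correlation). Macrophage markers (0.06, adjusted p = 0.292) and hepatocyte markers (-0.00, adjusted p = 0.281) did not differ as lists. On the deficient diet 3 of 13 iron-sulfur assembly genes fell, Iscu (-0.18), Hscb (-0.29) and Nfs1 (-0.20), where the list did not pass (adjusted p = 0.0836). Of 19 fatty acid synthesis genes 6 rose and 2 fell (median 0.26, list adjusted p = 0.0528), and the hypoxia targets Ankrd37 (1.35), Kdm3a (0.39) and Aldoa (0.25) rose while their list did not pass (adjusted p = 0.168). The adipocyte gene Fabp4 rose by 0.87. Single genes in this paragraph and the next were named after their values were seen.

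In D2 livers 5 of 12 T and NK cell markers were lower and 1 higher than in B6. Gzmb (-2.79), Klrb1c (-1.58), Gzma (-0.82), Nkg7 (-0.61) and Thy1 (-0.36) were lower and Cd3g (0.23) higher, at a list median of -0.23 (adjusted p = 0.0397, but adjusted p = 0.393 with an estimated correlation). Of 16 female-biased genes 10 were lower and 1 higher, at a median of -0.83 (adjusted p = 0.041, but adjusted p = 0.601 with an estimated correlation), and of 30 respiratory chain genes 13 were lower and 3 higher (median -0.07, adjusted p = 0.0414, but adjusted p = 0.601 with an estimated correlation). For the difference between strains of the enrichment effect, 6 of 24 cell cycle genes passed adjusted over the list alone, at a median of 0.50 (adjusted p = 2.24e-08, but adjusted p = 0.173 with an estimated correlation). The bile duct keratin Krt19 (-1.07) and the erythroid Alas2 (1.66) differed. For the difference of the deficiency effect the male-biased median was 0.34 (adjusted p = 2.57e-05, but adjusted p = 0.64 with an estimated correlation). The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were expressed on each of the 30 arrays, with lowest levels of 11.09, 12.02, 8.77 and 7.40.

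The mice were regrouped at random up to 100 times per result, the real grouping included. For enrichment 1 of 100 groupings gave as many genes as the real one, which itself counts (real 469, highest other 395). The same held for deficiency (1 of 100; 1703, other 3), enrichment in B6 (1; 1228, other 97), deficiency in B6 (1; 378, other 201), deficiency in D2 (1; 986, other 114), the difference of enrichment effects (1; 234, other 6), the F tests over diets (1; 2471, other 8) and of interaction (1; 200, other 29), opposite genes (1; 45, other 0) and strain (1; 10563, other 6752). For these results only the real grouping gave as many genes. A regrouping leaves the real differences inside its groups, which widens the spread and lowers its count. It also takes no account of slide or scan day, so the share of 1 in 100 does not exclude chance. With slide as a block enrichment gave 302 and deficiency in B6 65, and deficiency in B6 gave 180 without B6 deficient mouse 4. No regrouping was fitted with a block or without a mouse, so these counts cannot be set against the 395 and 201. For these 2 results the structure of the samples is not excluded. For enrichment in D2 2 of 100 groupings did (19, other 220) and for the difference of deficiency effects 3 of 100 (4, other 10), with 1 other grouping giving far more than 19. These shares are under 0.05 as well. But the count of 4 fell to 0 with slide as a block (limma, 1711 unadjusted), where the plain test without a block gave 3. It fell to 1 without D2 balanced mouse 3. The regroupings take no account of slide or scan day, so the difference of deficiency effects stays uncertain. The grouping with 220 genes, which also gave the 395 for enrichment, followed scan day in its D2 part. Its stand-in for D2 balanced held 3, 1 and 1 arrays of scan days 1, 2 and 3 and its stand-in for D2 enriched 0, 1 and 4, which points to a structure of the samples. Its stand-ins for B6 balanced and B6 enriched held 0, 3 and 2 and 0, 2 and 3 arrays, and so did not part by scan day in this way. The grouping with 201 genes for deficiency in B6, which also gave the 10, did not part by scan day: its stand-ins for B6 balanced and B6 deficient held 1, 1 and 3 and 0, 2 and 3 arrays of the scan days, and 4 of 5 mice of the latter were B6 deficient mice. With scan day as a block 24 genes passed for enrichment in D2 and 806 for enrichment, and with slide 17 and 302. The regrouping of strains with 6752 genes left 26 of the 30 mice with their own strain, and that with the next highest count, 2896, left 22.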
